A study of Cucumis sativus with 6 samples.

How the data were processed

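RNA from female flower buds of cucumber (Cucumis sativus), taken 7 days before anthesis, was sequenced from 3 wild type and 3 Cshec2 mutant samples. The design text calls the samples of each genotype biological replicates, and the labels give the genotype and number of each library. Libraries were made from total RNA extracted with Trizol, using an Illumina kit, per the labels' protocols. HISAT2, HISAT and DESeq2 are named in the submitters' processing notes without version or role. The genome build and the gene annotation are not given in the sources used here.

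One deposited table was used, with a value for each gene and library, and per the file headers it lists genes that differ between the genotypes. It holds 1589 genes, so every gene in it had already been selected by the authors, and no unselected gene was analysed here. The deposited per-library values are a normalised expression signal whose unit the header does not name; they are not whole numbers, and their low values are not multiples of one step. Read depth is therefore unknown, and no interval or detection floor that needs it is given. The FDR column holds the adjusted p-value of the authors' comparison, with 0.05 as its largest entry after rounding. The log2 fold change column is that of the authors, with a smallest absolute value of 0.585, which equals the log2 of the 1.5-fold limit in the table's name. One gene, Csa5G644580, has dashes in place of both entries, so whether it met these limits is not shown.

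Gene names were taken from the Swiss-Prot and NR protein descriptions in the table, which describe 1564 of the 1589 genes. None of the identifiers was found in the RefSeq gene table (0 matches), so no coordinates are given. A name such as MYB106 is therefore the described similarity of a cucumber gene and not its established identity. Of the genes, 60 carry an identifier of the newGene form.

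Mutant and wild type were compared with limma 3.58.1 in R 4.3.3, with a trend in the variance, on log2(value + 1), without a filter on low values. P-values were adjusted by the Benjamini-Hochberg method over the genes of the table, with a threshold of 0.05. Fold changes from limma are on the log2(value + 1) scale, which understates the change of genes with low values. Because the genes had been selected on the same libraries, the number that passes is not an independent count of changed genes, and adjusted p-values over this table are smaller than over a whole transcriptome. Means are given with the SD of 3 libraries. On simulated data for this comparison with 1589 genes, 100 were changed by 1 on the log2 scale and 100 by 2. Of these, 69% and 91% were recovered, with 5 false calls. The simulation left most genes unchanged and gave both genotypes the same spread. Here every gene had been selected and wild type varied more, so these rates do not carry over to this table.

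Gene lists were defined by keywords before the data were examined. There were 23 lists, of which 19 had at least 3 passing members and were tested; the brassinosteroid (1 member), C2H2 zinc finger (2), ovule and seed (2) and pollen and anther (0) lists were not. In each list the passing genes that were higher and lower were set against those of the remaining described genes by a two-sided Fisher's exact test, in scipy 1.17.1, with Benjamini-Hochberg adjustment over the 19 lists. That test counts each gene as an independent observation, although all genes were measured in the same libraries, and related genes may vary together. The genes named were chosen by a rule also set before the data were examined. It took the 10 genes with the largest log2 change in each direction among passing genes with an informative description, ranges that did not overlap and a mean of at least 1 in the higher genotype. It added up to 4 passing members of each list with the smallest p-values, and all members of the cytokinin list. This gave 91 genes, and the text says where another gene was chosen after its values were seen.

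The alternatives were median-of-ratios scaling, limma without the trend, a mean value of at least 1, pseudocounts of 0.1 and 0.5, the replicate number as a block, each library left out in turn, and other thresholds. A comparison with wild type library 1 as the only control and a keyword search that included Pfam domain names were added after the data had been seen. Random sets and bootstrap intervals used 10000 draws. Figures were drawn with matplotlib 3.10.9.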

Results

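Expression was compared in female buds of wild type cucumber and of plants carrying the Cshec2 mutation, 7 days before anthesis, with 3 libraries per genotype. CsHEC2 is the gene after which the mutant is named, and the series title places it in fruit wart formation and cytokinin biosynthesis. The question was which genes differ in expression when it is mutated. The values summed to 23592, 24068 and 24173 in the 3 mutant libraries and to 41126, 44182 and 59342 in the wild type libraries, over the 1589 listed genes alone. None of the descriptions names HECATE (0 genes), and neither CsGL3 nor CsTu could be matched to a described gene, so the expression of the mutated gene was not analysed here and the genotype labels were not checked by it.

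Stress and defence genes were lower in mutant buds more often than the other listed genes (100% against 79.6% of passing genes, Fisher's exact test, adjusted p = 4.99e-05). The test counts genes as independent, so this p-value does not measure variation between samples. Among genes changed at least 2-fold, of which 509 were lower and 49 higher, the list was still 100% lower, but the test did not pass (adjusted p = 0.682). Csa4G285760 of that list, described as peroxidase 2, measured 0.953 ± 0.132 in the mutant and 19.3 ± 5.88 in wild type (mean ± SD, n = 3, here and below). Of the lower genes in none of the lists, Csa2G238880, described as non-symbiotic hemoglobin 1, measured 2.29 ± 0.275 in the mutant and 73.4 ± 10.6 in wild type, a log2 change of -4.49 (SE 0.17, limma adjusted p = 4.2e-05). Csa3G142960, described as a protease inhibitor, measured 0.381 ± 0.117 against 12.5 ± 2.91. Other lower genes with large changes were less even in wild type, as given below. In the other direction, Csa6G439940, described as calcium-dependent protein kinase 8, measured 18.1 ± 0.967 in the mutant and 3.41 ± 0.243 in wild type, a log2 change of 2.12 (SE 0.14, limma adjusted p = 0.000552).

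In the authors' deposited table, 293 genes are listed as higher and 1296 as lower in the mutant (81.6% lower). With limma, 1473 of the 1589 genes passed an adjusted p of 0.05, of which 293 were higher and 1180 lower (80.1% lower). The 116 genes that did not pass were all listed as lower. Scaling the libraries by the median of ratios over the table left 293 higher and 225 lower genes (43.4% lower), and moved the median log2 change by 0.74, from -0.77 to -0.02. That scaling centres a table made only of selected genes, most of them listed as lower, so it takes calls from lower genes by construction. A call lost under it, here and below, therefore does not decide whether a gene was lower. The 3 mutant and 3 wild type values did not overlap for 1494 genes; the 10% that chance gives for 3 against 3 applies to unselected genes, and these had been selected for differing between the same libraries. Among passing genes, 49 were higher and 509 lower by at least 1 on the log2 scale, and 7 were higher and 97 lower by at least 2.

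The wild type libraries differed more among themselves than the mutant libraries did. The median SD of the log2 values was 0.28 in wild type and 0.13 in the mutant, and the SD was larger in wild type for 78.5% of genes. Wild type libraries 2 and 3 were at least 4-fold above wild type library 1 for 29 genes in which library 1 lay within 2-fold of the highest mutant library. Uneven wild type values were not confined to these 29. Among the named lower genes, Csa6G014830 lay at 9.33, 47.2 and 132 in wild type libraries 1 to 3, against a mutant mean of 0.806. Csa3G646010 lay at 3.87, 27.6 and 71.4 against 0.749, and Csa6G448740 at 14.5, 26.6 and 164 against 2.74. With wild type library 1 as the only control, a comparison chosen after seeing the data, 261 higher and 1007 lower genes passed limma. In that fit the spread comes from the 3 mutant libraries alone, and the single wild type library is assumed to vary like them, so the counts do not show that calls withstand the wild type spread.

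**Figure D1:**
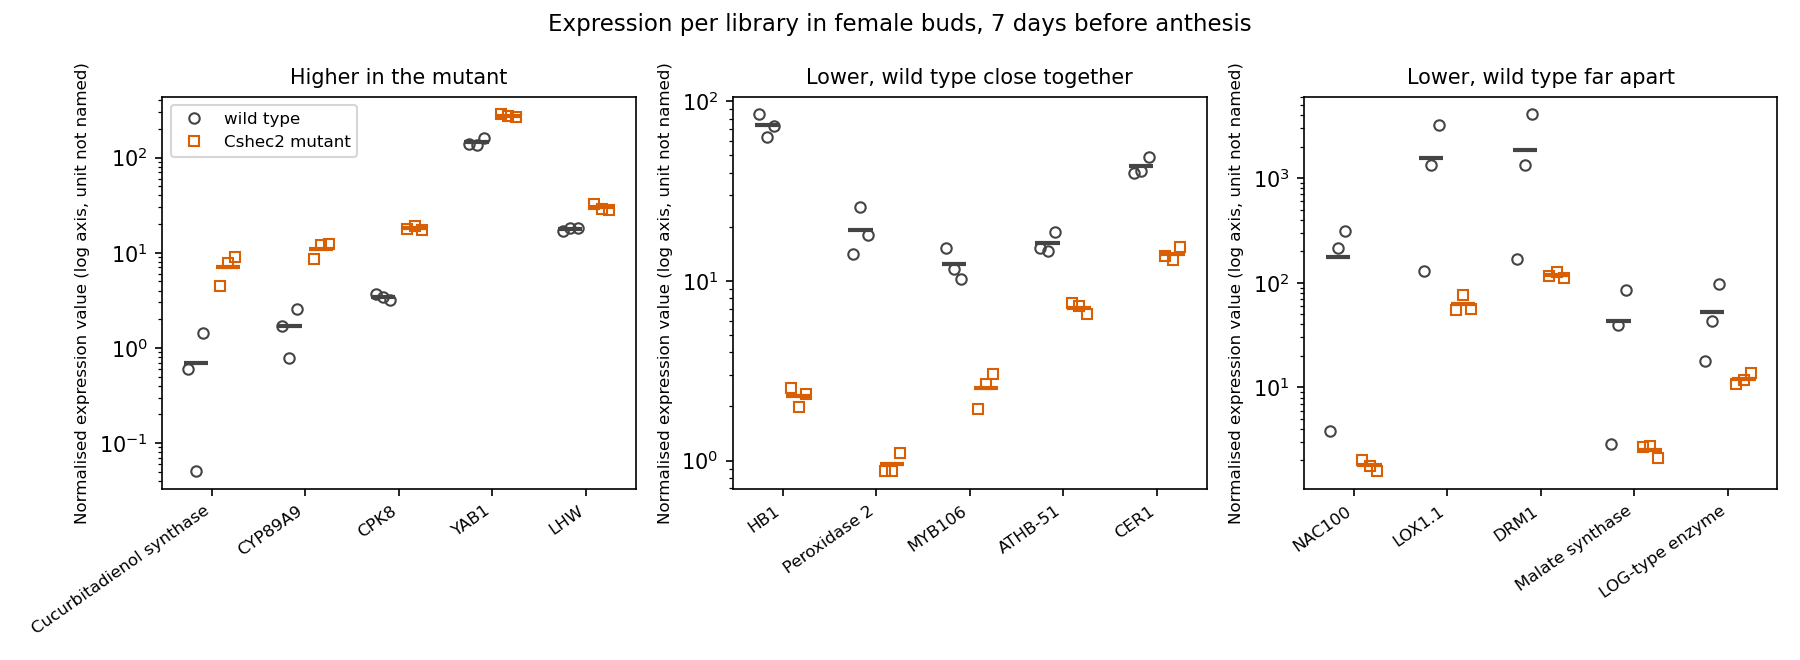
Normalised expression values (log axis, unit not named in the table) of 15 described genes in each wild type library (circles) and each Cshec2 mutant library (squares), with horizontal lines at the means of 3 libraries; replicates 1 to 3 run from left to right. In the left panel the mutant values lie above wild type and in the middle panel they lie under it, while in the right panel wild type library 1 lies nearer to the mutant libraries than the other wild type libraries do.

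The 10 higher genes named for their log2 change were taken from genes with an informative description only. Over all passing genes, 7 were higher by at least 2 on the log2 scale and 2 by at least 3. Of the 10, Cucumis_sativus_newGene_607 is described as cucurbitadienol synthase, the enzyme that makes the cucurbitacin skeleton. It measured 7.08 ± 2.35 in the mutant and 0.691 ± 0.695 in wild type, a log2 change of 2.29 (SE 0.36, limma adjusted p = 0.00274). In the authors' deposited table its log2 fold change is 0.77 with an FDR of 0.0403, although its mutant mean lay 10.2-fold above its wild type mean. Cucumis_sativus_newGene_1136 has 3.46 there. With a pseudocount of 0.1 in limma the log2 changes of these 2 genes were 3.67 and 3.65. Why the deposited value of the first is so much lower was not tested. Csa6G088170 (CYP89A9) lay 6.54-fold above its wild type mean of 1.69 ± 0.892 (log2 change 2.20, SE 0.29), with Csa6G088160 (CYP81E8) at 6.73 ± 2.09 against 1.15 ± 0.983 and Csa6G088710 (CYP87A3) at 10.1 ± 2.87 against 2.57 ± 1.14. Csa3G903540, described as beta-amyrin 11-oxidase, measured 31.7 ± 8.15 against 7.44 ± 3.71. Csa6G504720, described as CYP84A1, measured 17.1 ± 1.14 against 4.13 ± 1.03, and Csa3G901690, described as TORNADO 2, measured 5.10 ± 1.51 against 0.92 ± 0.216. Csa1G611290, described as beta-glucosidase 24, rose from 0.449 ± 0.309 to 4.80 ± 3.50, and Cucumis_sativus_newGene_1136, described as the long-chain-alcohol oxidase FAO4A, from 0.0723 ± 0.0335 to 2.03 ± 0.0304. The terpenoid and cucurbitacin list as a whole held 2 higher and 2 lower passing genes (adjusted p = 0.368), and 2 higher and 1 lower after median-of-ratios scaling, among them squalene monooxygenase Csa7G069710, which fell to 16.0 ± 3.02 from 32.1 ± 7.25 and did not pass after that scaling (adjusted p = 0.883).

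All 3 members of the cytokinin list, a hormone class that promotes cell division, were lower in the mutant and passed limma, against 80.4% lower among the other passing genes. For 3 members, all lower is the most extreme outcome in that direction, and it still gave an adjusted p of 1 (Fisher's exact test). The test could therefore not tell a lowered list of this size from the other genes. None passed after median-of-ratios scaling (0 of 3), which by its construction takes calls from lower genes in this table. The title of the series names cytokinin biosynthesis, so the list is not independent evidence of direction. Csa6G358680, described as a LOG-type phosphoribohydrolase, an enzyme that releases active cytokinin, measured 2.52 ± 0.963 in the mutant and 7.98 ± 3.16 in wild type, a log2 change of -1.32 (SE 0.35, limma adjusted p = 0.0128). A further LOG-type gene, Csa6G141420, measured 12.1 ± 1.56 against 52.8 ± 40.8, a log2 change of -1.73 (SE 0.55, limma adjusted p = 0.0215). Its wild type libraries lay at 17.9, 42.7 and 97.7, and it did not pass without mutant library 1, mutant library 2 or wild type library 2, with limma adjusted p of 0.064, 0.0574 and 0.0584. Csa5G644580, described as cytokinin hydroxylase, measured 0.158 ± 0.0718 against 0.726 ± 0.34, with a limma adjusted p of 0.0151 that became 0.0516 without mutant library 1. In the authors' deposited table this is the last of the 1589 genes and the 1 gene without an FDR or a log2 fold change. How it came to be listed is therefore not known, and its place among the 3 lower members may not rest on the authors' limits.

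Stress and defence was the 1 list of 19 that passed. Adjusted over the list alone, each of the 19 lists had as many passing members as when adjusted over all genes of the table, 59 in this list. Of its 65 members, 0 were higher, 59 were lower and 6 did not pass, against 79.6% lower among the other described genes (Fisher's exact test, adjusted p = 4.99e-05). After median-of-ratios scaling 0 members were higher and 17 lower. All 15 WRKY genes, 14 peroxidase genes and 16 glutathione transferase genes in the list were lower and passed, and 3 of 6 heat shock genes passed. Csa7G236280, described as WRKY71, measured 0.244 ± 0.0827 in the mutant and 2.42 ± 0.408 in wild type, and the glutathione transferase gene Csa3G133880 measured 0.315 ± 0.08 against 3.75 ± 1.14. Every member with a call was lower. Among genes changed at least 2-fold the list was still 100% lower, but the test no longer passed (adjusted p = 0.682). At that threshold 509 genes were lower and 49 higher, which leaves little room for a list to differ by being lower.

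The 8 members of the jasmonate list were all described as lipoxygenases, which oxidise fatty acids. All 8 were lower, against 80.3% among other genes (Fisher's exact test, adjusted p = 0.635). For 8 members this is the most extreme outcome in that direction, so the test could not have passed for lower genes. After median-of-ratios scaling 6 were lower. Csa4G286950, described as lipoxygenase 2 of the chloroplast, fell to 96.7 ± 12.2 from 300.4 ± 33.3, and Csa4G286940, described as lipoxygenase 2.3, to 93.7 ± 14.1 from 278 ± 13.5. Whether reads were divided between such similar genes is not known, so their separate values are uncertain. The linoleate 9S-lipoxygenase genes were less even among wild type libraries. Csa2G024440 lay at 131, 1341 and 3265 in wild type and at 62.3 ± 12.1 in the mutant, and its log2 change of -3.74 (limma adjusted p = 0.0158) did not pass without wild type library 2 (adjusted p = 0.0536) or after median-of-ratios scaling (log2 change -2.81, adjusted p = 0.0727). Against wild type library 1 alone its log2 change was -1.08. Csa2G023940, also described as a linoleate 9S-lipoxygenase, lay at 169, 1265 and 2940 in wild type and at 66.0 ± 11.9 in the mutant. Its log2 change of -3.69 (limma adjusted p = 0.0114) still passed without wild type library 2 (adjusted p = 0.0401) and after median-of-ratios scaling (adjusted p = 0.048). Against wild type library 1 alone it was -1.35. The list's median log2 ratio of wild type library 3 to library 1 was 1.12, at percentile 99.4 of random lists matched on expression. Its members did not share that shift evenly. The chloroplast genes Csa4G286950 and Csa4G286940 lay at 339 and 285 in library 1 and at 281 and 263 in library 3. The list mixes these with linoleate 9S-lipoxygenases, so its median does not describe all of its genes.

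In the cuticle and wax list, 3 genes were higher and 32 lower of 37 (adjusted p = 0.368), and 3 higher and 5 lower after median-of-ratios scaling. Csa6G079750, described as ECERIFERUM 1, which acts in alkane formation for wax, measured 14.1 ± 1.18 in the mutant and 43.3 ± 4.73 in wild type, a log2 change of -1.55 (SE 0.15, limma adjusted p = 0.000848). The glycerol-3-phosphate acyltransferase gene Csa7G412840 measured 0.235 ± 0.0605 against 2.04 ± 0.4. Csa1G340430, described as WIN1, a regulator of wax and cutin genes that was counted in the ethylene list, measured 2.12 ± 0.491 against 7.31 ± 1.56, and did not pass after that scaling (adjusted p = 0.0766). In the cell wall list, 9 genes were higher and 36 lower of 49, or 80.0% lower against 80.4% of the other genes (adjusted p = 1), and 9 were higher and 9 lower after median-of-ratios scaling. The xyloglucan endotransglucosylase gene Csa1G422480 measured 8.84 ± 1.62 against 92.4 ± 30.4, and the exopolygalacturonase-like gene Csa7G037590 measured 35.3 ± 1.39 against 195 ± 67.0. The median log2 ratio of wild type library 3 to library 1 was -0.39 in the cuticle and wax list and -0.42 in the cell wall list.

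Among trichome and epidermis regulators, 4 genes were higher and 14 lower of 18 (adjusted p = 0.97), and 4 higher and 3 lower after median-of-ratios scaling, which moved the median log2 change from -0.72 to 0.08. The keywords also took in 7 genes of the trichome birefringence family, which are named for a trichome phenotype and act in wall modification. Csa3G824850, described as MYB106, a regulator of epidermal cell outgrowth, measured 2.55 ± 0.556 in the mutant and 12.4 ± 2.57 in wild type, a log2 change of -1.91 (SE 0.21, limma adjusted p = 0.00105). Csa3G748220, described as the homeobox-leucine zipper protein ATHB-51, measured 7.10 ± 0.506 against 16.2 ± 2.14, and did not pass after that scaling (adjusted p = 0.303). The MYB family held 3 higher and 15 lower genes (adjusted p = 1), and 3 higher and 7 lower after that scaling, including Csa4G416980 (MYB96) at 0.493 ± 0.25 against 4.39 ± 0.727.

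Floral organ and meristem regulators went both ways, with 8 higher and 12 lower genes of 21 (adjusted p = 0.191), and 8 higher and 1 lower after median-of-ratios scaling. All 3 YABBY genes were higher, including Csa5G160210, described as YABBY 1, a regulator of organ polarity, at 274 ± 9.22 in the mutant and 145 ± 13.7 in wild type. Of 3 WUSCHEL genes 2 were higher and 0 lower, and all 3 MADS genes were lower. Of 9 NAC genes 8 were lower and 1 was higher, the latter Csa6G425760 by 2.83-fold (log2 change 1.36, SE 0.21, limma adjusted p = 0.00252). The NAC100-like gene Csa3G824990 had the lowest log2 change among the named genes, -4.63 (SE 1.48, limma adjusted p = 0.0224). Its wild type libraries lay at 3.82, 216 and 314 against 1.79 ± 0.215 in the mutant, and it did not pass when any library other than wild type library 1 was left out (adjusted p between 0.0562 and 0.0766) or after median-of-ratios scaling (adjusted p = 0.0751). Its log2 change was -0.79 against wild type library 1 alone, -6.55 without that library and -0.67 in the authors' deposited table, so its rank rests on wild type libraries 2 and 3. The bHLH family, to which the HECATE proteins belong, held 4 higher and 3 lower genes (adjusted p = 0.191), and 4 higher and 1 lower after that scaling. Among them Csa3G002970, described as LHW, a regulator of vascular development, measured 29.9 ± 2.37 against 17.8 ± 0.944, and Csa1G074400, described as bHLH162, measured 1.20 ± 0.351 against 8.60 ± 1.40.

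The ethylene list held 0 higher and 23 lower genes of 25 (Fisher's exact test, p = 0.0136, adjusted p = 0.129), and 0 higher and 4 lower after median-of-ratios scaling. Of its members, 17 were described as ethylene-responsive transcription factors, and 2 were methylenesterol methyltransferases matched only by spelling. In the auxin list, 3 genes were higher and 13 lower, including Csa7G398090 (ARG2) at 91.9 ± 11.6 against 574 ± 298. The gibberellin list held 2 higher and 2 lower genes, the abscisic acid list 2 and 4, the phloem and vascular list 7 and 12, the photosynthesis list 2 and 6, the cell cycle list 2 and 5, the transport list 9 and 20, and the phenylpropanoid list 3 and 23. None of these lists passed. After median-of-ratios scaling the higher and lower genes were 3 and 3 for auxin, 2 and 1 for gibberellin, 2 and 0 for abscisic acid, 7 and 1 for phloem and vascular genes, and 2 and 0 for photosynthesis. They were 2 and 0 for the cell cycle, 9 and 2 for transport and 3 and 4 for phenylpropanoids. In the abscisic acid list the 8'-hydroxylase gene Csa6G504430 rose to 1.34 ± 0.152 from 0.222 ± 0.137, while the 8'-hydroxylase gene Csa4G056600 measured 52.9 ± 7.45 against 88.6 ± 16.5, a log2 change of -0.72 (limma adjusted p = 0.0121) that became 0.19 after that scaling. In the transport list the aquaporin gene Csa3G826650 fell to 27.3 ± 3.59 from 95.8 ± 9.05.

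**Figure D2:**
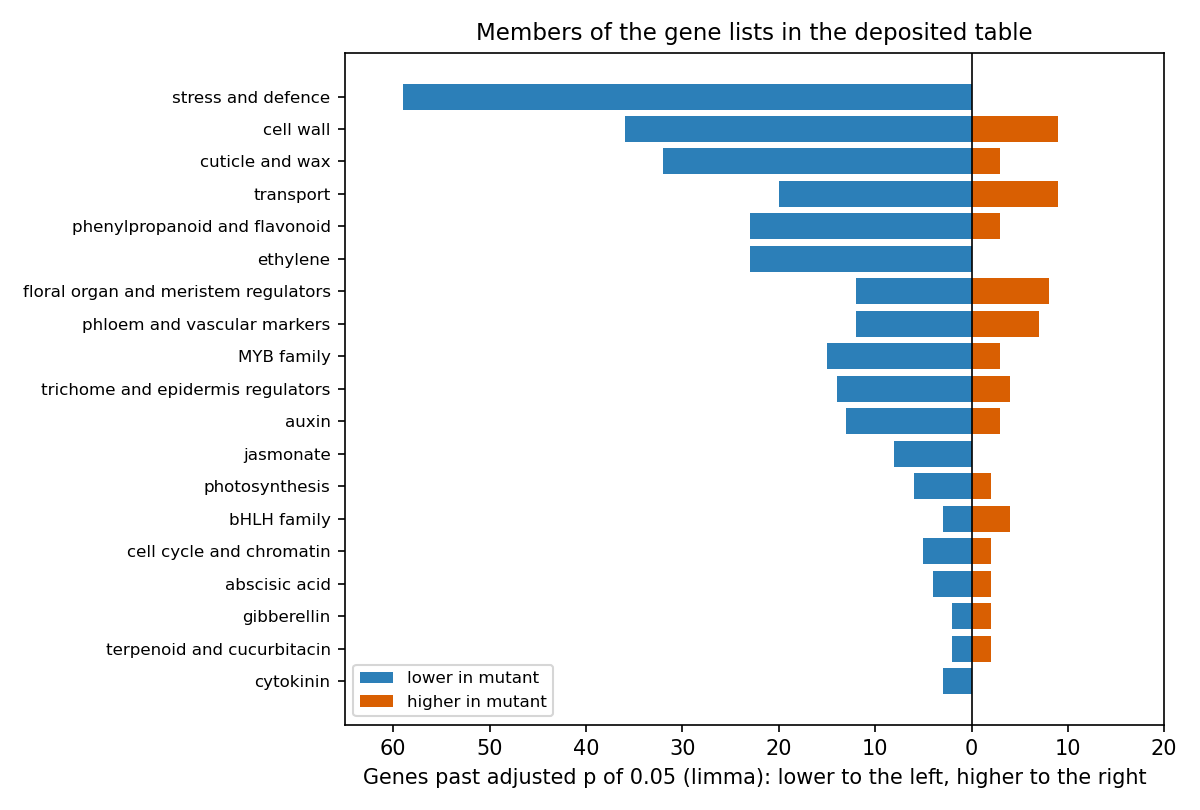
Number of genes past a limma adjusted p of 0.05 in each of the 19 tested lists, with genes lower in the Cshec2 mutant to the left of 0 and genes higher to the right. The stress and defence bar holds 59 lower and 0 higher genes, and before any rescaling most bars are longer on the left, as in the table as a whole (80.1% lower).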

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

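The comparison with wild type library 1 alone and the search of Pfam domain names were chosen after seeing the data. The main comparison used no filter on low values, so the alternative without one is the same comparison. CsHEC2 was matched to no gene, so no alternative was run for it.

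Median-of-ratios scaling over the table left 518 genes, 293 higher and 225 lower; by its construction it centres a table of selected genes. Under it 67 of 91 named genes kept their call, 20 no longer passed and 4 changed sign, with log2 changes of 0.19 for Csa4G056600 (CYP707A1), 0.25 for Csa5G139540 (PYL8), 0.13 for Csa7G375840 (KLCR2) and 0.25 for Csa2G010330 (photosystem II protein W). Requiring a 2-fold change left 558 genes, 49 higher and 509 lower, and 0 lists passed; stress and defence was still 100% lower (adjusted p = 0.682, against 8.3e-06 to 0.000351 under the other alternatives), beside a background in which most genes were lower; the cause was not tested.

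Leaving out each library in turn gave 1088 to 1525 genes, 263 to 289 higher and 823 to 1236 lower. The number of lists that passed was 1 to 2, the floral organ and meristem list joining without wild type library 2, and stress and defence stayed at 100% lower. Without the trend 1460 genes passed, 1374 with a mean of at least 1, 1486 with a pseudocount of 0.1 and 1478 with 0.5. With wild type library 1 alone 1268 passed, but the spread in that fit comes from the mutant libraries only (median SD 0.13, against 0.28 in wild type), so it is no check against the wild type spread.

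Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.09, -0.04 and -0.18 over genes. With the replicate number as a block 1392 genes passed. Read depth is unknown, so its limit on low values was not assessed.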

Other observations

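All tests below were chosen after the values were seen, except the scaling test at a log2 change of 1, the test of phloem and vascular genes and the splits of the libraries.

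The 29 genes at least 4-fold higher in wild type libraries 2 and 3 than in library 1, with library 1 within 2-fold of the highest mutant library, were defined by those values alone, and 9 of them match keywords of carbon and amino acid breakdown or starvation that were drawn up from them. The examples here were chosen after their values were seen. Malate synthase (Csa1G050360), an enzyme of the glyoxylate cycle, lay at 2.86, 39.3 and 86.0 in wild type libraries 1, 2 and 3 and at a mean of 2.52 in the mutant. Isocitrate lyase (Csa2G420990), of the same cycle, lay at 0.426, 8.79 and 17.6 and did not pass limma (adjusted p = 0.0524). The dormancy-associated gene Csa6G518000 (DRM1) lay at 167, 1332 and 4088 against a mutant mean of 119. Others of the 29 are described as regulators, such as NAC100, bHLH130, RAX2 and RAV2, or have no Swiss-Prot description. With all libraries 26 of the 29 passed limma, and with wild type library 1 as the only control, where the mutant libraries alone give the spread, 10 did. Their median absolute log2 change was 2.32 from limma and 0.84 in the authors' deposited table.

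Csa6G408210 and CsaUNG024780, also chosen after their values were seen, were listed at 0 in all 3 wild type libraries. Csa6G408210 measured 7.32, 7.57 and 8.47 in the mutant libraries, and CsaUNG024780 measured 11.7, 8.66 and 6.22. Neither has an informative description, and no fold is given against a value of 0.

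More genes were lower than higher in the mutant. High values in wild type libraries 2 and 3 alone are argued against, since the mutant mean lay below wild type library 1 for 79.5% of genes (95% interval 77.5 to 81.5); this covers the listed genes only, whose selection used library 1 as well and so favours such a share. A scaling error of 0.4 on the log2 scale in the authors' comparison cannot be told apart from a real excess at the threshold set before the data were examined: after moving every deposited log2 change up by 0.4, 280 genes were lower and 271 higher by at least 1, a ratio of 1.03 (0.87 to 1.23). At 2 further thresholds, added after the values were seen, the ratio was 2.48 (1.71 to 3.63) for changes of at least 1.5. An error of 0.4 would not leave that ratio if real changes were as large and as many in both directions, which is not known here. For changes of at least 2 the ratio was 1.77 (0.86 to 3.8), which decides nothing. Larger errors were not tried, and the intervals count genes as independent, so the 3 ratios do not settle the question. The table holds no unchanged genes by which the scaling might be checked, and an effect of the mutation stays open.

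The wild type libraries differed from one another, and 1 scaling factor per library is argued against, since only 81.2% of genes (79.2 to 83.1) lay within 1 of the median log2 ratio of library 3 to library 1. The share required was set after the values were seen, and the interval counts genes as independent. How far scatter between replicates alone would widen these ratios was not tested, so the argument is weak. More phloem and vascular tissue in library 3 stays open, the median ratio of the phloem and vascular list exceeding that of stress and defence genes by 0.3 (-0.1 to 0.6). The keywords of that list included lectin and took in lectin receptor kinases such as Csa1G071280 and Csa3G806260, so it does not measure that tissue alone. Ethylene, jasmonate and stress genes exceeded cuticle and cell wall genes by 0.41 (0.2 to 0.72), but opposite shifts stay open: cuticle and wall genes lay below the other genes, by -0.51 (-0.66 to -0.34), while the first group, with a median of 0.02 against 0.08 over the table, did not lie clearly above them (-0.07, -0.2 to 0.2), its stress list having a median of -0.07 and its jasmonate list 1.12, with 6 of its 8 lipoxygenase genes higher in library 3 than in library 1. Carbon starvation or darkness was tested with keywords drawn up from the 29 genes: the 18 matching genes outside them had a median log2 ratio of 0.47 (0.35 to 1.09), at percentile 94 of matched random lists, short of the 95 required, so this stays an open hypothesis. The labels give no time of day, position or batch for the libraries, and all have the same genotype, so the design names no difference between them.

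Cucurbitadienol synthase (Cucumis_sativus_newGene_607), Csa6G088160, Csa6G088170, Csa6G088710 and Csa3G903540 were picked after their values were seen, from general knowledge of cucurbitacin synthesis. A hypothesis is that these 5 genes may share regulation. Their deviations within genotypes had a mean pairwise correlation of 0.89 over the 6 libraries, against -0.21 to 0.47 in random sets of 5 other higher genes. In 5 of 5, wild type library 2 was the lowest wild type library and mutant library 1 the lowest mutant library, as for 44.4% and 26.4% of other higher genes. Because the genes were picked after their values were seen, this comparison cannot decide for the hypothesis, and reads shared between similar genes were not analysed here.

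Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes as the real one, which is itself: 1473 genes passed limma in the real split and 0 in every other, where at most 70 had an unadjusted p under 0.05. With 10 splits a share under 0.05 cannot be reached, and the genes had been selected on the real split.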
